A study of Homo sapiens with 6 samples.

How the data were processed

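Polyadenylated RNA from 6 samples of human cells labelled MCF-7 was sequenced in pairs of reads on an Illumina NovaSeq instrument, per the labels' protocols. 3 samples carry a control short hairpin RNA and 3 a short hairpin RNA against ZNF408. The groups and the replicate numbers were taken from the sample titles.

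The authors quantified transcripts with kallisto, per the submitters' processing notes, which also name DESeq2 and the builds GRCh38 and hg38. The version of kallisto, its index and any trimming of reads are not given in the sources used here. The deposited files give, per transcript, estimated counts, which kallisto divides among transcripts that share sequence and which need not be whole. They also give TPM, a length-scaled relative abundance, per the file headers, beside the length and the effective length of each transcript. TPM is scaled to the same total in each library and so holds no depth, and it was used in a single alternative fit. Because kallisto shares reads among similar transcripts, values of paralogs and of genes with alternate haplotype sequences are less certain than those of other genes. Strand was not stated, so overlapping genes on opposite strands cannot be told apart.

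Each file listed 188753 transcripts. Of these, 169754 were matched by identifier to the GENCODE 29 transcript set (GRCh38) and 15522, absent from that set of reference chromosomes, through the GENCODE 29 symbol table. The remaining 3477 had no symbol and were left out of the gene tests. They held 0.674% to 0.727% of the reads. Estimated counts were summed per gene symbol, so that alternate copies of a gene such as HLA-A were added together, and rounded to whole numbers, giving 35551 symbols. The libraries held 15006585 to 15820902 estimated reads, at which a gene at 10 CPM has at least 149 reads and a count of 0 allows up to 0.191 to 0.201 CPM (3 counts). These limits cover counting error only, since reads without molecular identifiers are not independent molecules. Replicates differed by more than sampling noise (chi-square per degree of freedom 3.11 to 7.27 between libraries of one group), so none was treated as a repeat of another.

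Genes with enough reads were kept by edgeR's filterByExpr (14269 genes, 8750 with reads removed), libraries were scaled by TMM, and groups were compared with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) without covariates, with 4 residual degrees of freedom. p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The standard error of a log2 fold change was taken as its size divided by the square root of the F statistic. Gene lists were tested with limma's camera (limma 3.58.1) on log2 CPM at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over the 39 lists with at least 5 tested members. The members passing within a list are counted by the adjustment over all genes and by one over the list alone.

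The design, the gene lists, the rule for naming genes and all alternatives except the GC correction were set before the data were examined. The genes named are ZNF408 and SETD1A, then the 10 with the largest positive and the 10 with the largest negative log2 fold change among genes past the threshold, of a mean CPM of at least 5, annotated as protein coding, whose groups do not overlap (5712 genes met these conditions), then in each list up to 4 members with the smallest p. CD274, B2M, HLA-A, HLA-B, HLA-C, TAP1, ESR1, PGR and MKI67 could be named whatever their values. The genes of this rule that the main fit tested, all but ESR1 and PGR, were tested under the alternatives, whatever came of them, with MYLIP, CDH1, AXL, KRT7, KRT18, EPCAM, GATA3, FOXA1 and 6 LXR targets besides. Names are those of GENCODE 29, with a newer symbol in brackets where it differs.

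The alternatives were RLE size factors, library size alone, no filter on low counts, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1), an offset for effective transcript length, counts by gene ID, protein-coding genes alone, the replicate number as a block, and leaving out each library. The GC correction subtracted from each library a loess curve (span 0.5) of its log2 CPM deviations on the GC content of the transcripts, as an offset in edgeR. GC values existed for 99.99% of the genes tested.

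The fits were tested on simulated data. With 50 genes each changed 1.25-, 1.5-, 2- and 4-fold among 14079 genes in a simulated knockdown against control, edgeR recovered 56%, 78%, 94% and 100%, and 16 of its 180 calls (8.89%) were false. In a second simulation with a GC trend added to 14085 genes, 2045 calls were false without the GC correction and 17 with it. Both simulations changed few genes, and the second gave all 3 knockdown libraries the same GC trend. Their rates need not hold for the real libraries, where many genes were called and GC slopes differed within groups. Text tables were handled with Python 3.11.15 and pandas 2.3.3.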

Results

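Messenger RNA was measured by paired-end sequencing of polyadenylated RNA in human cells labelled MCF-7, a line derived from a luminal, oestrogen receptor positive breast cancer. The 6 libraries formed 2 groups of 3: cells with a control short hairpin RNA, whose samples carry the genotype label WT, and cells with a short hairpin RNA against ZNF408, a gene for a zinc finger protein in which variants are known to cause an inherited disease of the retinal vessels. Each library held between 15006585 and 15820902 estimated reads, and between 18967 and 19377 gene symbols had reads in each. Here, control means the control hairpin and knockdown the ZNF408 hairpin. Normalised CPM (read counts scaled to library size) are means ± SD over 3 libraries, and log2 fold changes are knockdown over control ± SE from edgeR's quasi-likelihood test. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

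The comparison of both groups asked how gene expression differed with the ZNF408 hairpin, with immune genes as the interest stated in the series title. The sample titles name no second hairpin and no rescue. Other effects of the hairpin therefore cannot be told apart from those of lower ZNF408. ZNF408 (GRCh38 chromosome 11, 46700818 to 46705912, plus strand) was at 16.5, 17.2 and 16.1 CPM in the 3 control libraries and at 10.03, 10.5 and 9.25 CPM in the 3 knockdown libraries, so it was lower in each library labelled as a knockdown. It fell to 0.597 of its control level (log2 fold change -0.74 ± 0.12, edgeR adjusted p = 9.03e-05). Of the tested members, 16 of 21 NF-kB targets, 13 of 19 interleukins and growth cytokines and 18 of 24 unfolded protein response genes rose in the knockdown libraries, whereas 22 of 24 sterol synthesis and 19 of 30 S phase genes fell. With a correlation estimated from the libraries, the unfolded protein response and S phase lists did not pass (adjusted p = 0.0510 and 0.0510), though both passed after a GC correction (0.0328 each). CXCL8, which encodes a neutrophil chemokine, rose from 172 ± 9.58 to 1236 ± 111 CPM, and HSPA5, which encodes the chaperone BiP of the endoplasmic reticulum, rose from 616 ± 1.88 to 3122 ± 59.4 CPM. DHCR7, which encodes a late enzyme of cholesterol synthesis, fell from 245 ± 11.99 to 73.4 ± 6.68 CPM.

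**Figure D1:**
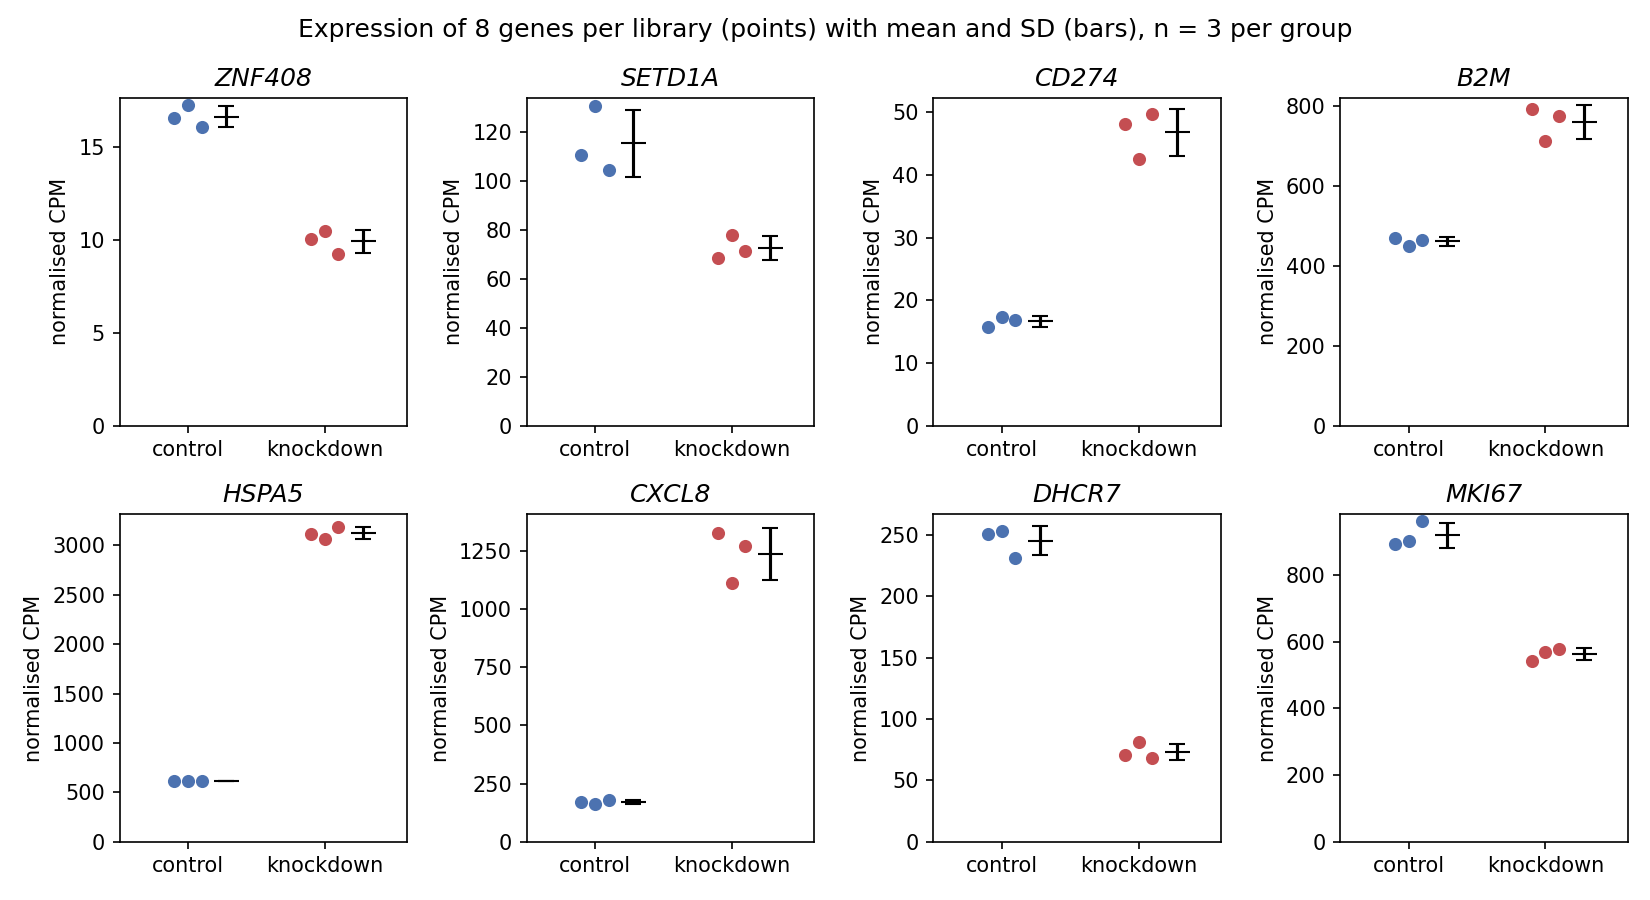
Normalised CPM of 8 genes (vertical axes, from 0) in the 3 control and 3 knockdown libraries (points), with the mean and SD of each group (bars, n = 3). ZNF408 lay between 16.1 and 17.2 CPM in the control libraries and between 9.25 and 10.5 CPM in the knockdown libraries.

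Of 14269 genes tested, 3217 were higher and 3284 lower in the knockdown libraries at a Benjamini-Hochberg adjusted p of at most 0.05, which is 45.6% of the genes tested. Most of these differences were small: the median absolute log2 fold change of the genes past the threshold was 0.44, and 617 genes changed at least 2-fold, 380 higher and 237 lower. Libraries of one group correlated at 0.987 to 0.989 (Pearson's r of log2 CPM across genes, which are not independent replicates), and libraries of different groups at 0.968 to 0.975. With log2(TPM + 1) values in limma, 2305 genes were higher, 1675 lower and 410 changed at least 2-fold. With genes of a mean CPM of at least 5 alone, 303 did.

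A trend with base composition ran through the libraries. The slope of a library's log2 expression on transcript GC content was 0.094, 0.16 and 0.0051 per 10% GC in the control libraries and -0.11, 0.0011 and -0.15 in the knockdown libraries, and log2 fold changes correlated with GC content at a Spearman's rho of -0.378 across genes. A correction for this trend, chosen after seeing the data, left 5439 of the 6501 genes past the threshold in the same direction. In all it called 3670 genes higher and 3467 lower, with 417 and 172 changed at least 2-fold.

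**Figure D2:**
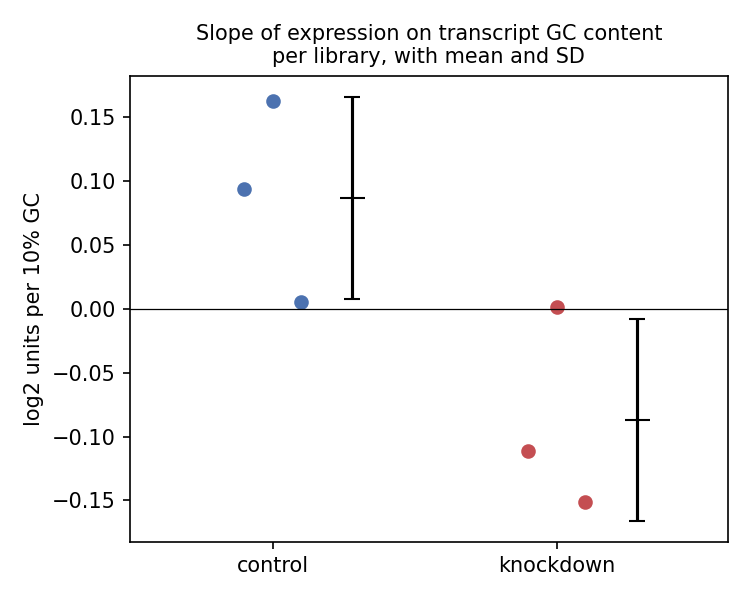
Slope of log2 expression on transcript GC content (vertical axis, log2 units per 10% GC) for each library (points), with the mean and SD of each group (bars, n = 3). The slopes ran from 0.0051 to 0.16 in the control libraries and from -0.15 to 0.0011 in the knockdown libraries.

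The 10 largest rises among protein-coding genes of at least 5 CPM on average were those of ABCA1, the cholesterol exporter (log2 fold change 4.001 ± 0.19, from 1.96 ± 0.808 to 31.5 ± 2.66 CPM), IL24 (3.21 ± 0.092), FOS (3.05 ± 0.20), CXCL8 (2.85 ± 0.068), EGR1 (2.80 ± 0.098), SPX (2.79 ± 0.21), CSF2 (2.75 ± 0.080), MMP1 (2.73 ± 0.071), CXCL2 (2.71 ± 0.082) and IL1A (2.51 ± 0.092). Of these, IL24, CXCL8, CSF2, CXCL2 and IL1A encode secreted cytokines or chemokines, FOS and EGR1 encode transcription factors of the immediate early response, and MMP1 encodes a collagenase. The 10 largest falls were those of TENT5B (-2.26 ± 0.17), MYH15 (-2.23 ± 0.21), CMKLR1, the chemerin receptor (-2.03 ± 0.21), TNS1 (-1.95 ± 0.16), IFIT1, an interferon-induced gene (-1.77 ± 0.087), DHCR7 (-1.74 ± 0.070), FASN, fatty acid synthase (-1.71 ± 0.086), ZNF771 (-1.65 ± 0.18), the nucleoside transporter gene SLC29A2 (-1.61 ± 0.13) and CAVIN2 (-1.61 ± 0.10). The edgeR adjusted p was at most 2.60e-06 for each of these 20 genes, and the fall of TNS1 was not past the threshold in limma on log2(TPM + 1) (log2 fold change -0.90, adjusted p = 0.0539, 6.84e-38 to 0.0539 over the alternatives). That fit also gave smaller changes for ABCA1 (2.25), SPX (1.89), MYH15 (-1.06), CMKLR1 (-0.98) and FASN (-0.98), all still past the threshold. With the effective length offset, TNS1 (-1.03) and FASN (-1.04) changed less as well.

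Gene lists set before the data were examined were tested as groups, and 21 of the 39 lists with at least 5 tested members passed camera's test at a preset correlation of 0.01. With a correlation estimated from these libraries, 3 of the 21 remained (sterol biosynthesis, interleukins and growth cytokines, and NF-kB targets). Some genes belong to several lists, so the list results are not independent of one another. fry, which asks whether the genes of a list move on balance one way and does not compare them with other genes, called 33 lists. After the GC correction 20 of the 21 kept their call, all but MYC targets, and 7 of the 21 with an estimated correlation. These 7 were the 3 above and the unfolded protein response, S phase, G2/M and epithelial-mesenchymal transition lists. In all, 25 lists passed after the correction at the preset correlation. The oestrogen response, basal and myoepithelial, TGF-beta and BMP, nuclear-encoded oxidative phosphorylation and endothelial lists gained the call. Since 3217 of all 14269 genes tested were higher and 3284 lower, called members in both directions are no trait of a list by themselves.

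**Figure D3:**
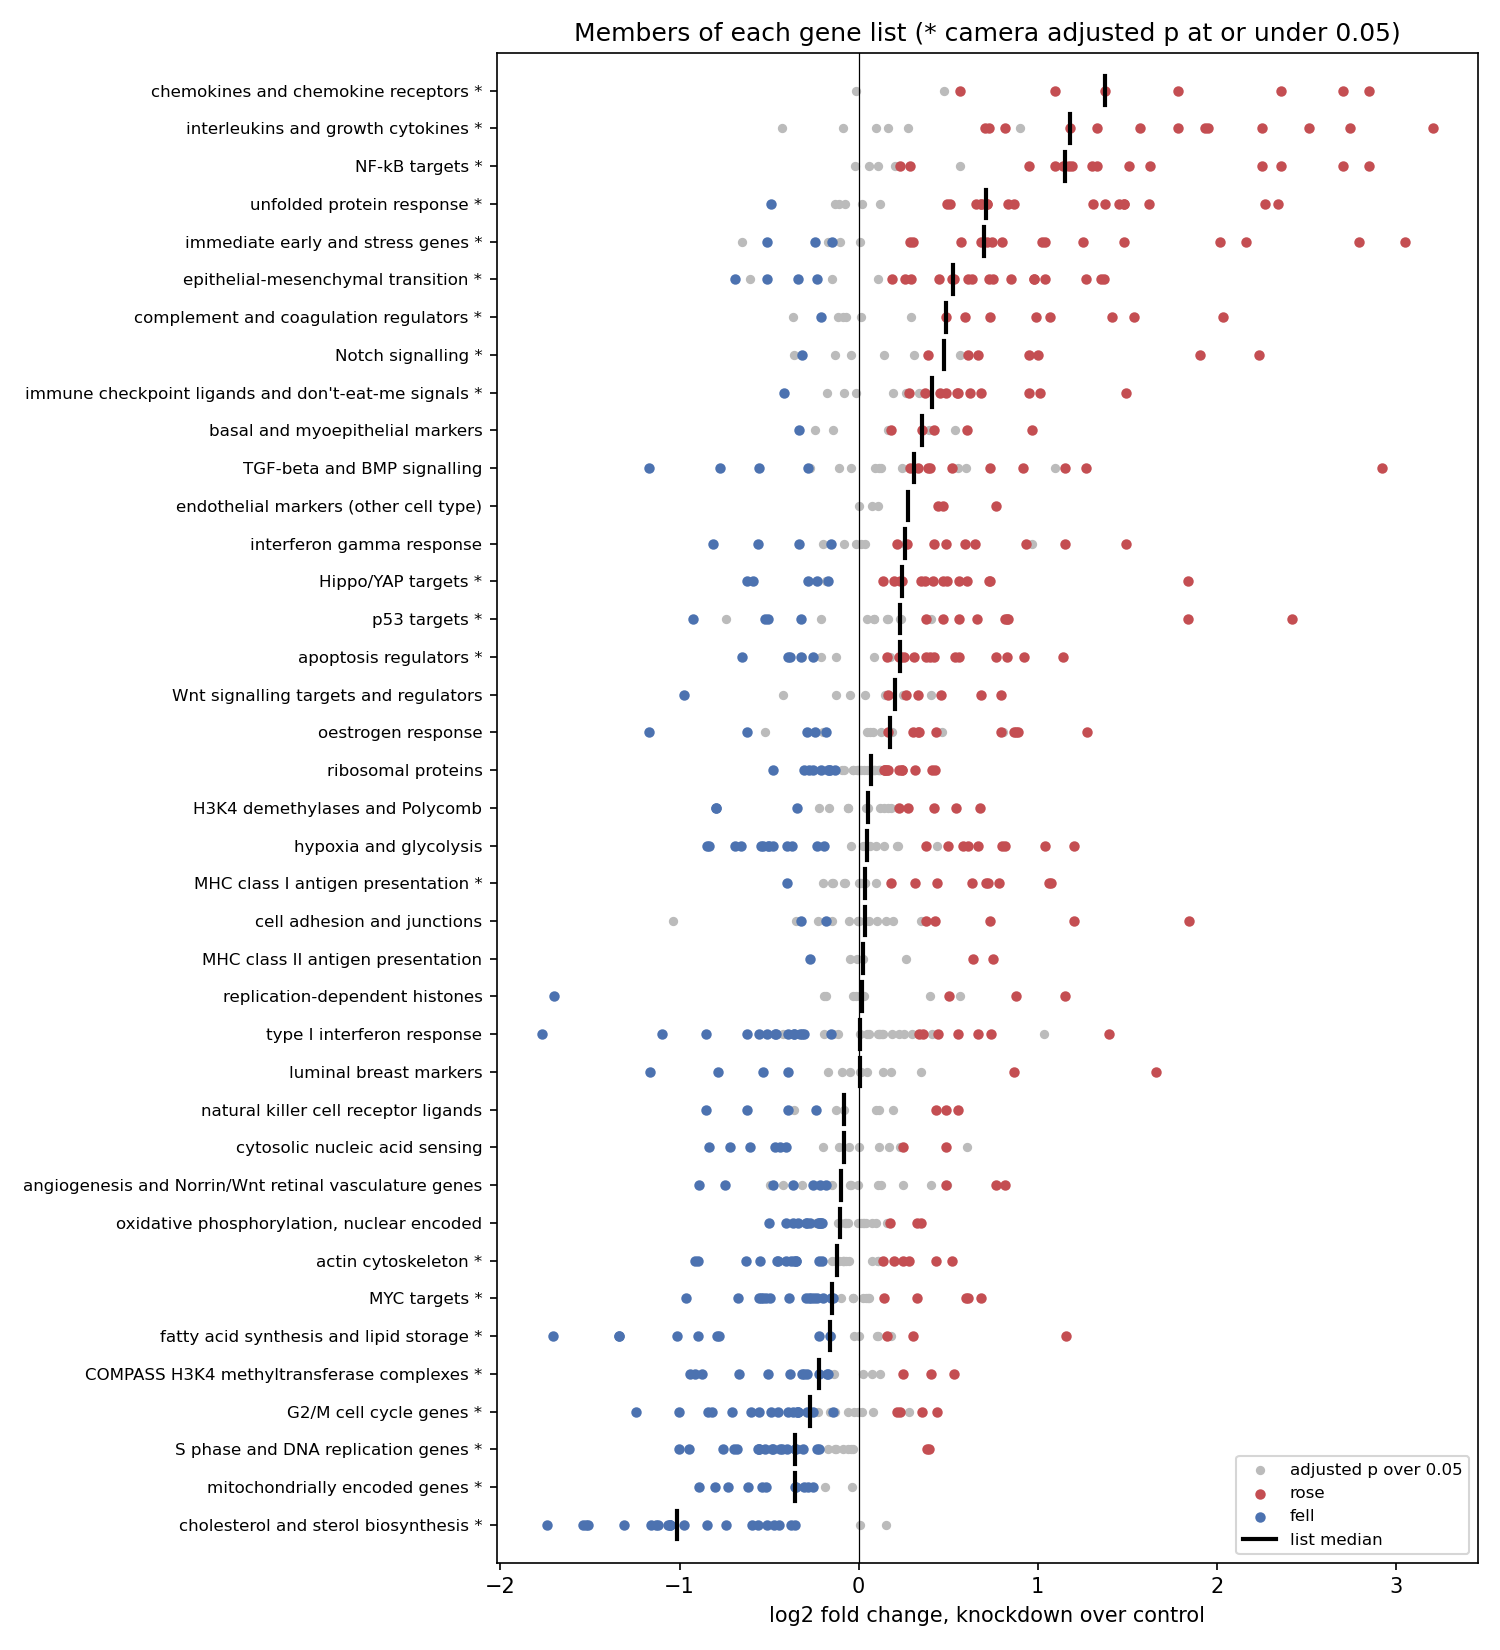
Log2 fold change, knockdown over control (horizontal axis), of each tested member (points) of the 39 gene lists (vertical axis, ordered by median), with members that rose, fell or did not pass the edgeR threshold in different colours, the list median as a bar and an asterisk for lists past camera's threshold. Medians ran from -1.01 for sterol biosynthesis to 1.38 for chemokines.

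Genes of cholesterol and sterol biosynthesis fell together. Of 24 tested members, 0 rose, 22 fell and 2 did not pass (1 and 22 adjusted over the list alone), with a median log2 fold change of -1.01 (camera adjusted p = 3.65e-11, adjusted p = 0.0399 with an estimated correlation). The smallest adjusted p-values belonged to ACAT2 (-1.54 ± 0.061), DHCR7 (-1.74 ± 0.070), DHCR24 (-1.16 ± 0.054) and FDPS (-1.05 ± 0.051), all enzymes of the pathway, with edgeR adjusted p at most 7.79e-10. In the list for fatty acid synthesis and lipid storage, 3 rose, 9 fell and 6 did not pass of 18 (also 3 and 9 adjusted over the list alone). The median was -0.16 (camera adjusted p = 0.0417, adjusted p = 0.198 with an estimated correlation). SCD, the stearoyl-CoA desaturase, fell from 713 ± 16.3 to 282 ± 12.05 CPM (-1.34 ± 0.050), and FADS2 (-1.34 ± 0.060), FASN (-1.71 ± 0.086) and ACLY (-1.01 ± 0.051) also fell, with edgeR adjusted p at most 1.17e-09.

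The unfolded protein response, which is induced when misfolded proteins build up in the endoplasmic reticulum, rose: 18 rose, 1 fell and 5 did not pass of 24 (also 18 and 1 adjusted over the list alone). The median was 0.71 (camera adjusted p = 1.29e-07, adjusted p = 0.0510 with an estimated correlation). HSPA5 (2.34 ± 0.042), DDIT3, which encodes the transcription factor CHOP (2.27 ± 0.079), HSP90B1 (1.37 ± 0.052) and PPP1R15A (1.48 ± 0.059) had the smallest p-values (edgeR adjusted p at most 8.16e-11). Among immediate early and stress genes, 15 rose, 3 fell and 4 did not pass of 22 (also 15 and 3 adjusted over the list alone), with rises of DUSP1 (2.16 ± 0.062), EGR1 (2.80 ± 0.098), KLF6 (1.04 ± 0.053) and FOS (3.05 ± 0.20). The median was 0.70 (camera adjusted p = 1.63e-04, adjusted p = 0.301 with an estimated correlation). In the list of p53 targets, 9 rose, 4 fell and 10 did not pass of 23 (also 9 and 4 adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.0357, adjusted p = 0.198 with an estimated correlation). GDF15 (2.42 ± 0.10) and GADD45A (1.84 ± 0.064), both also known as stress-induced genes, rose most clearly, along with TNFRSF10B (0.56 ± 0.050) and the cell cycle inhibitor gene CDKN1A (0.66 ± 0.063). Among apoptosis regulators, 14 rose, 5 fell and 5 did not pass of 24 (14 and 6 adjusted over the list alone). The median was 0.23 (camera adjusted p = 0.0455, adjusted p = 0.198 with an estimated correlation). The members with the smallest p-values there were BIRC3 (1.14 ± 0.067), BIRC2 (0.77 ± 0.064) and MCL1 (0.42 ± 0.048), known as inhibitors of cell death, and TNFRSF10B, a death receptor gene. edgeR's adjusted p was at most 5.47e-06 for each gene named for these 4 lists.

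Cytokine genes rose. Of 19 interleukins and growth cytokines, 13 rose, 0 fell and 6 did not pass (also 13 and 0 adjusted over the list alone). The median was 1.18 (camera adjusted p = 5.19e-08, adjusted p = 0.0399 with an estimated correlation). CSF3, the gene of granulocyte colony-stimulating factor, rose from 97.4 ± 3.95 to 377 ± 9.89 CPM (1.95 ± 0.055) and IL1B also rose (1.93 ± 0.057), beside IL24 and CSF2. Of 9 chemokines and chemokine receptors tested, 7 rose, 0 fell and 2 did not pass (also 7 and 0 adjusted over the list alone), including CXCL1 (1.10 ± 0.057) and CXCL3 (1.38 ± 0.12). The median was 1.38 (camera adjusted p = 9.32e-05, adjusted p = 0.157 with an estimated correlation). CXCL1, CXCL2 and CXCL3 are close copies of one another, so reads may have been divided between them. Of 21 NF-kB targets, 16 rose, 0 fell and 5 did not pass (17 and 0 adjusted over the list alone). The median was 1.15 (camera adjusted p = 4.78e-09, adjusted p = 0.0399 with an estimated correlation). This list shares CXCL8, CXCL1, CXCL2, CCL2 and CCL20 with the chemokine list, and IL6 and LTB with the interleukin list. The results of these lists therefore rest partly on the same genes. IL6 rose from 49.8 ± 4.48 to 238 ± 11.1 CPM (2.25 ± 0.071) and SOD2, mitochondrial superoxide dismutase, from 219.5 ± 10.4 to 678 ± 17.5 CPM (1.63 ± 0.052). Among complement and coagulation regulators, 8 rose, 1 fell and 6 did not pass of 15 (also 8 and 1 adjusted over the list alone). The median was 0.49 (camera adjusted p = 0.0229, adjusted p = 0.181 with an estimated correlation). C3 (1.42 ± 0.060), the complement inhibitor gene CD55 (1.07 ± 0.057), tissue factor gene F3 (0.73 ± 0.056) and C1S (2.03 ± 0.16) rose. For every gene named among these 4 lists the edgeR adjusted p was at most 2.22e-07.

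Genes of antigen presentation and immune recognition moved in both directions. CD274, which encodes the checkpoint ligand PD-L1 (GRCh38 chromosome 9, 5450503 to 5470566, plus strand), rose 2.81-fold from 16.6 ± 0.858 to 46.8 ± 3.72 CPM (log2 fold change 1.49 ± 0.092, edgeR adjusted p = 9.29e-09). Of 18 immune checkpoint ligands and don't-eat-me signals, 11 rose, 1 fell and 6 did not pass (also 11 and 1 adjusted over the list alone). The median was 0.41 (camera adjusted p = 0.00307, adjusted p = 0.157 with an estimated correlation). CD47, the ligand that restrains phagocytosis (0.62 ± 0.058), PVR (0.49 ± 0.056) and NT5E, the ectonucleotidase CD73 (0.37 ± 0.052), rose with CD274. In the MHC class I antigen presentation list, 9 rose, 1 fell and 11 did not pass of 21 (also 9 and 1 adjusted over the list alone), the median was 0.038 and the mean 0.24 (camera adjusted p = 0.0493, adjusted p = 0.258 with an estimated correlation). With the GC correction 11 of the list rose and 2 fell, at a median of 0.21 (camera adjusted p = 0.00344, adjusted p = 0.0897 with an estimated correlation). B2M, the light chain of class I molecules (GRCh38 chromosome 15, 44711487 to 44718877, plus strand), rose from 461 ± 10.9 to 759.8 ± 42.4 CPM (0.72 ± 0.051). HLA-B (1.07 ± 0.063), HLA-A (0.63 ± 0.064), HLA-C (0.71 ± 0.068) and the peptidase gene ERAP1 (0.78 ± 0.066) rose as well. The peptide transporter gene TAP1 did not pass (0.038 ± 0.077, edgeR adjusted p = 0.717), but did after the GC correction (0.14, adjusted p = 0.0404, 0.0404 to 0.978 over the alternatives). Of the HLA-A, HLA-B and HLA-C reads, 99.97%, 98.7% and 98.9% were assigned to transcripts outside the reference chromosomes, such as alternate haplotype sequences, and these genes share reads with one another, so their values are uncertain. Counted by the primary gene ID alone, HLA-B had a log2 fold change of 1.96 and HLA-C lost its call (log2 fold change 0.73, adjusted p = 0.178, 5.16e-19 to 0.178 over the alternatives). Of 7 tested MHC class II genes, 2 rose, 1 fell and 4 did not pass (also 2 and 1 adjusted over the list alone): CTSS (0.75 ± 0.15) and HLA-DMA (0.64 ± 0.22) rose and RFX5 (-0.27 ± 0.060) fell, the last not past the threshold in limma on log2(TPM + 1) (adjusted p = 0.117, 9.95e-05 to 0.117 over the alternatives). CIITA, the class II activator gene, did not pass (0.27 ± 0.13, edgeR adjusted p = 0.121). It was higher past the threshold after the GC correction (adjusted p = 0.0336, 0.0336 to 0.576 over the alternatives) and lower with the effective length offset (-0.33) or limma on log2(TPM + 1) (-0.19). The median was 0.022 (camera adjusted p = 0.547, adjusted p = 0.577 with an estimated correlation). The HLA-DMA call rested on single libraries, since leaving out control replicate 1 or 3 or knockdown replicate 2 or 3 raised its adjusted p to 0.0933, 0.0737, 0.0991 and 0.0693 (0.00701 to 0.173 over the alternatives). DESeq2, limma on log2(TPM + 1) and the effective length offset did not call it either. Of the HLA-DMA reads, 96.4% were assigned to transcripts outside the reference chromosomes.

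Interferon-stimulated genes were divided. In the type I interferon response list, 7 rose, 15 fell and 19 did not pass of 41 (8 and 15 adjusted over the list alone), and the median was 0.0086 where the mean and camera's test pointed down (mean -0.054, camera adjusted p = 0.397, adjusted p = 0.393 with an estimated correlation). IFIT1 fell from 111 ± 5.97 to 32.4 ± 4.16 CPM (-1.77 ± 0.087), and ISG15 (-0.85 ± 0.069), OAS3 (-0.55 ± 0.068) and IFIT3 (-0.51 ± 0.067) fell too. In the interferon gamma response list, 9 rose, 4 fell and 8 did not pass of 21 (11 and 4 adjusted over the list alone). The median was 0.26 (camera adjusted p = 0.0670, adjusted p = 0.249 with an estimated correlation). The adhesion molecule gene ICAM1 (1.15 ± 0.055) and IRF1 (0.60 ± 0.074) rose and SOCS3, a feedback inhibitor of cytokine signalling, fell (-0.81 ± 0.090). Of 16 cytosolic nucleic acid sensing genes, 2 rose, 6 fell and 8 did not pass (3 and 6 adjusted over the list alone), with falls of MAVS (-0.72 ± 0.057), EIF2AK2 (-0.40 ± 0.059), TMEM173 (STING1, -0.61 ± 0.092) and SAMHD1 (-0.44 ± 0.066), the last not past the threshold in limma on log2(TPM + 1) (adjusted p = 0.0701, 8.42e-09 to 0.0701 over the alternatives). The median was -0.082 (camera adjusted p = 0.235, adjusted p = 0.344 with an estimated correlation). Of 13 natural killer cell receptor ligands, 3 rose, 4 fell and 6 did not pass (also 3 and 4 adjusted over the list alone). The median was -0.081 (camera adjusted p = 0.781, adjusted p = 0.807 with an estimated correlation). With the GC correction 5 of the list rose and 3 fell, at a median of 0.010, and camera's direction turned up (adjusted p = 0.917). PVR and MICB (0.55 ± 0.072) rose and ULBP3 (-0.85 ± 0.13) and BAG6 (-0.40 ± 0.065) fell. BAG6 lost its call in limma on log2(TPM + 1) and by gene ID (adjusted p = 0.0625 and 0.139, 4.45e-12 to 0.139 over the alternatives) and shrank to -0.25 after the GC correction, and MICB gave -0.019 (adjusted p = 0.963, 1.87e-10 to 0.963 over the alternatives) when counted by the primary gene ID alone. Of the BAG6 and MICB reads, 97.0% and 95.8% were assigned to transcripts outside the reference chromosomes, so the values by gene ID rest on few of their reads. Each gene named here as rising or falling had an edgeR adjusted p of at most 1.57e-04.

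Most tested S phase and G2/M genes fell. Of 30 S phase and DNA replication genes, 2 rose, 19 fell and 9 did not pass (2 and 21 adjusted over the list alone). The median was -0.36 (camera adjusted p = 1.29e-05, adjusted p = 0.0510 with an estimated correlation). The replicative helicase genes MCM3 (-0.76 ± 0.052) and MCM5 (-1.004 ± 0.076), the polymerase gene POLD1 (-0.94 ± 0.076) and CHAF1A (-0.70 ± 0.064) had the smallest p-values. MCM5 was at -0.50 in limma on log2(TPM + 1) and at -0.56 with the effective length offset. Of 30 G2/M genes, 4 rose, 17 fell and 9 did not pass (5 and 17 adjusted over the list alone). The median was -0.27 (camera adjusted p = 0.00152, adjusted p = 0.298 with an estimated correlation). With the GC correction 4 of the list rose and 23 fell, and the list passed camera's threshold with an estimated correlation too (adjusted p = 0.0328). MKI67, the Ki-67 proliferation marker, fell from 919 ± 37.1 to 564 ± 18.4 CPM (-0.70 ± 0.049), and KIF20A (-1.24 ± 0.062), CDC20 (-1.004 ± 0.056) and PLK1 (-0.84 ± 0.058) fell with it. In the MYC target list, 5 rose, 16 fell and 9 did not pass of 30 (5 and 17 adjusted over the list alone), and the list was not past camera's threshold after the GC correction (adjusted p = 0.0746). The median was -0.15 (camera adjusted p = 0.0357, adjusted p = 0.361 with an estimated correlation). MYC itself rose (0.68 ± 0.060), while PHB (PHB1, -0.67 ± 0.054), BOP1 (-0.96 ± 0.090) and PA2G4 (-0.56 ± 0.052) fell. The largest edgeR adjusted p among the genes named for these 3 lists was 6.55e-07.

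The COMPASS complexes write methyl marks on lysine 4 of histone H3, and SETD1A, the catalytic subunit of one of them, was assayed elsewhere in the series. SETD1A (GRCh38 chromosome 16, 30957294 to 30984664, plus strand) fell from 115 ± 13.7 to 72.7 ± 4.86 CPM (-0.67 ± 0.082, edgeR adjusted p = 1.08e-05). Of 19 COMPASS genes, 3 rose, 12 fell and 4 did not pass (also 3 and 12 adjusted over the list alone), with falls of CXXC1 (-0.91 ± 0.078), MEN1 (-0.87 ± 0.079) and PAGR1 (-0.94 ± 0.11) at edgeR adjusted p of at most 4.73e-06. The median was -0.22 (camera adjusted p = 0.0357, adjusted p = 0.298 with an estimated correlation). ZNF408 and SETD1A have GC-rich transcripts (61.3% and 62.3% GC), and after the GC correction their log2 fold changes were -0.53 ± 0.11 and -0.43 ± 0.049, both still past the threshold (edgeR adjusted p = 4.15e-04 and 3.06e-07). The median of the COMPASS list was -0.16 after that correction. Among H3K4 demethylases and Polycomb genes, 5 rose, 3 fell and 11 did not pass of 19 (also 5 and 3 adjusted over the list alone). The median was 0.051 (camera adjusted p = 0.522, adjusted p = 0.532 with an estimated correlation). JARID2 (0.68 ± 0.063) and EZH1 (0.54 ± 0.10) rose and CBX2 (-0.80 ± 0.097) and CBX8 (-0.80 ± 0.17) fell, the last not past the threshold in limma on log2(TPM + 1) (adjusted p = 0.0779, 6.55e-07 to 0.0779 over the alternatives). Of 12 replication-dependent histone genes tested, 3 rose, 1 fell and 8 did not pass (also 3 and 1 adjusted over the list alone), namely HIST1H2AG (H2AC11, 1.15 ± 0.24), HIST1H1C (H1-2, 0.50 ± 0.11) and HIST2H2BE (H2BC21, 0.88 ± 0.23) upward and HIST2H2AC (H2AC20, -1.70 ± 0.49) downward. The median was 0.017 (camera adjusted p = 0.401, adjusted p = 0.468 with an estimated correlation). The HIST2H2AC call was lost without knockdown replicate 3 (adjusted p = 0.0563, 0.00657 to 0.0563 over the alternatives), and polyadenylated RNA captures few histone transcripts of this class.

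Luminal breast markers ran from 0 reads to an average of 197 ± 13.9 CPM for KRT7 (SD, n = 6), with a list median of 5.93 CPM and 4 of 17 under 1 CPM. KRT8 was at 113 ± 10.9 CPM in the control and 65.4 ± 3.56 CPM in the knockdown libraries, KRT18 at 157 ± 3.37 and 119 ± 5.46 CPM, EPCAM at 6.12 ± 0.749 and 6.17 ± 0.614 CPM, FOXA1 at 6.20 ± 1.27 and 5.51 ± 1.04 CPM, and GATA3 at 3.74 ± 1.53 and 3.86 ± 0.303 CPM. ESR1, the oestrogen receptor gene, was at 0.535 ± 0.270 CPM in the control and 0.708 ± 0.217 CPM in the knockdown libraries, PGR at 0.200 ± 0.177 and 0.170 ± 0.195 CPM, and CDH1, the E-cadherin gene, at 0.691 ± 0.396 and 0.882 ± 0.116 CPM (SD, n = 3 each). The filter on low counts removed ESR1 and PGR. CDH1 did not pass (0.35 ± 0.47, edgeR adjusted p = 0.571), and limma on log2(TPM + 1) gave -0.88. KRT7, KRT18, EPCAM, FOXA1, GATA3, CDH1, TFF1, AXL, TWIST1 and TWIST2 were chosen after their values were seen. TFF1 had 0 reads in all 6 libraries, which allows up to 0.201 CPM in the shallowest library (3 counts, counting error only). In the same libraries VIM, which encodes the mesenchymal intermediate filament vimentin, was at 2335 ± 28.9 CPM in the control and 1448 ± 25.8 CPM in the knockdown libraries, and the receptor gene AXL at 1418 ± 48.9 and 1208 ± 45.01 CPM. Of 32 epithelial-mesenchymal transition genes, 8 were under 1 CPM, TWIST1 and TWIST2 with 0 reads, at a list median of 28.5 CPM. Of 15 luminal markers tested, 2 rose, 4 fell and 9 did not pass (also 2 and 4 adjusted over the list alone), camera's direction being down and the median above 0. The median was 0.0061 (camera adjusted p = 0.820, adjusted p = 0.839 with an estimated correlation). XBP1, also a gene of the unfolded protein response (0.87 ± 0.061), and ELF3 (1.66 ± 0.20) rose, and the keratin genes KRT8 (-0.78 ± 0.076) and KRT19 (-1.16 ± 0.16) fell. In the oestrogen response list, 10 rose, 5 fell and 9 did not pass of 24 (13 and 5 adjusted over the list alone), with AREG (1.28 ± 0.16) and GREB1 (0.80 ± 0.14) higher and CELSR2 (-0.62 ± 0.11) lower. The median was 0.17 (camera adjusted p = 0.127, adjusted p = 0.344 with an estimated correlation). With the GC correction 12 of the list rose and 4 fell, at a median of 0.30. It then passed camera's threshold (adjusted p = 0.0378), but not with an estimated correlation (0.145). GREB1 and CELSR2 lost their calls with an offset for effective transcript length (adjusted p = 0.0672, 2.61e-07 to 0.111 over the alternatives, and 0.0501, 1.60e-07 to 0.292 over the alternatives) and in limma on log2(TPM + 1). Among the luminal and oestrogen response genes named as higher or lower, the largest edgeR adjusted p was 3.91e-04.

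**Figure D4:**
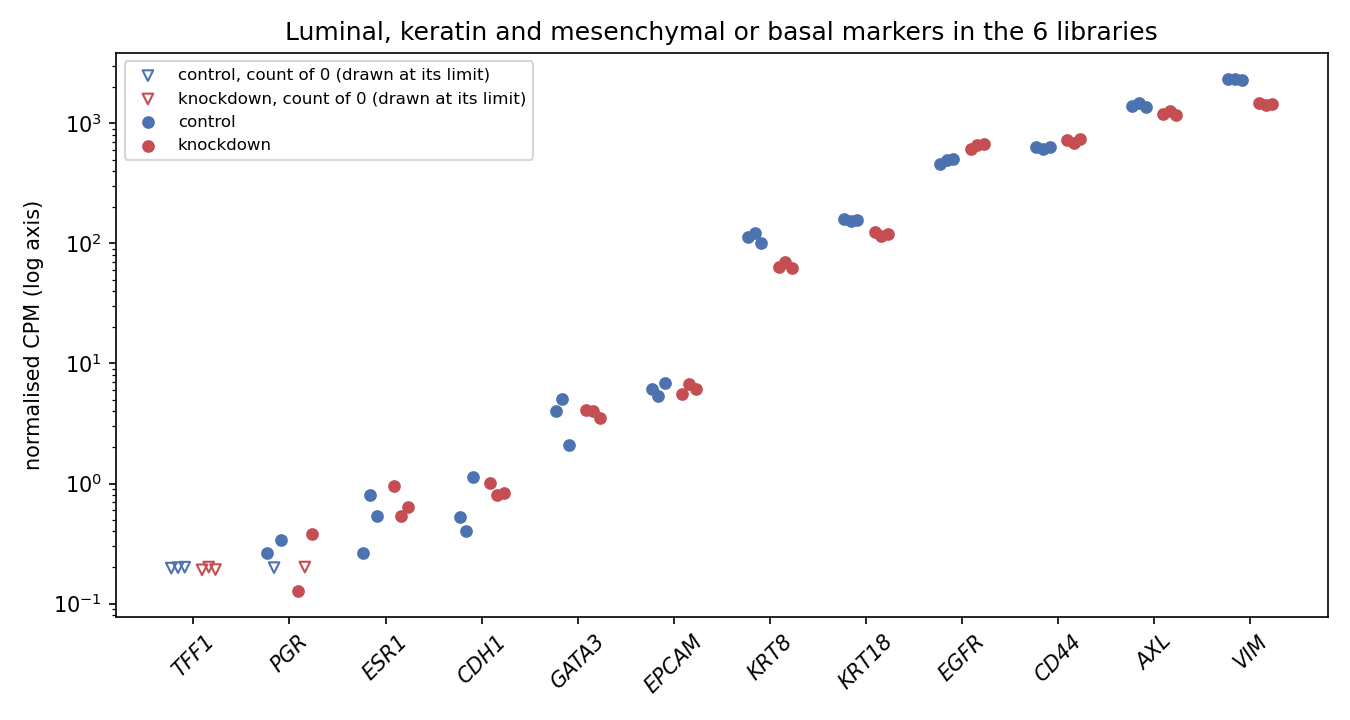
Normalised CPM (vertical axis, log scale) of luminal markers, keratins and basal or mesenchymal markers (horizontal axis) in the 3 control and 3 knockdown libraries (points), where open triangles stand for a count of 0 and are drawn at the limit it allows. ESR1 and CDH1 lay at or below 1.14 CPM in all 6 libraries, KRT18 lay between 114 and 160.5 CPM, and VIM between 1424 and 2360 CPM.

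Mesenchymal genes mostly rose. In the epithelial-mesenchymal transition list, 17 rose, 4 fell and 3 did not pass of 24 (17 and 5 adjusted over the list alone). The median was 0.53 (camera adjusted p = 0.00146, adjusted p = 0.181 with an estimated correlation). SERPINE1, the plasminogen activator inhibitor gene (1.27 ± 0.049), TGFBI (1.37 ± 0.061) and LOX, lysyl oxidase (1.04 ± 0.061), rose, whereas VIM, the most abundant member, fell (-0.69 ± 0.040). Among basal and myoepithelial markers, 5 rose, 1 fell and 5 did not pass of 11 (also 5 and 1 adjusted over the list alone), with rises of the laminin genes LAMC2 (0.97 ± 0.064) and LAMB3 (0.60 ± 0.059), of EGFR (0.42 ± 0.053) and of MYLK (0.35 ± 0.068). The MYLK call was lost with the effective length offset (adjusted p = 0.242, 1.88e-06 to 0.317 over the alternatives) and in limma on log2(TPM + 1). The median was 0.35 (camera adjusted p = 0.0632, adjusted p = 0.249 with an estimated correlation). The basal list passed camera's threshold after the GC correction (adjusted p = 0.0269), but not with an estimated correlation (0.152). Of 21 cell adhesion and junction genes, 5 rose, 2 fell and 14 did not pass (4 and 2 adjusted over the list alone). The median was 0.036 (camera adjusted p = 0.521, adjusted p = 0.529 with an estimated correlation). The claudin gene CLDN1 rose from 32.8 ± 1.42 to 118 ± 8.38 CPM (1.84 ± 0.074), F11R (0.73 ± 0.10) and the desmoglein gene DSG2 (0.43 ± 0.058) rose and CTNNB1, beta-catenin, fell (-0.18 ± 0.051, edgeR adjusted p = 0.00769; -0.28 in limma on log2(TPM + 1) and -0.33 with the effective length offset). In the actin cytoskeleton list, 6 rose, 13 fell and 11 did not pass of 30 (6 and 14 adjusted over the list alone). The median was -0.12 (camera adjusted p = 0.0357, adjusted p = 0.282 with an estimated correlation). Profilin gene PFN1 (-0.90 ± 0.052), ACTN4 (-0.91 ± 0.061), ACTB (-0.55 ± 0.039) and MYH9 (-0.63 ± 0.056) fell. Each of these genes apart from CTNNB1 had an edgeR adjusted p of at most 6.09e-04.

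Genes encoded by mitochondrial DNA fell: 0 rose, 11 fell and 2 did not pass of 13 (also 0 and 11 adjusted over the list alone). The median was -0.36 (camera adjusted p = 9.32e-05, adjusted p = 0.298 with an estimated correlation). MT-ATP6 (-0.80 ± 0.050), MT-CO3 (-0.73 ± 0.053), MT-CYB (-0.61 ± 0.048) and MT-ATP8 (-0.89 ± 0.073) had the smallest p-values (edgeR adjusted p at most 1.83e-07), although nuclear pseudogene copies can share their reads. The share of reads on mitochondrial genes was 5.13 ± 0.231% in the control and 3.90 ± 0.225% in the knockdown libraries (SD, n = 3 each; exact two-sided permutation p = 0.1, the smallest that 3 against 3 allows). Of 21 Hippo/YAP targets, 14 rose, 5 fell and 2 did not pass (14 and 6 adjusted over the list alone), with CYR61 (CCN1, 0.56 ± 0.042), TGFB2 (0.73 ± 0.055), F3 and GADD45A higher. The median was 0.24 (camera adjusted p = 0.0357, adjusted p = 0.298 with an estimated correlation). Of 14 Notch signalling genes, 7 rose, 1 fell and 6 did not pass (also 7 and 1 adjusted over the list alone). The median was 0.48 (camera adjusted p = 0.0229, adjusted p = 0.181 with an estimated correlation). The target gene HES1 (1.91 ± 0.12), the receptor gene NOTCH2 (0.61 ± 0.050) and the ligand genes JAG1 (0.66 ± 0.060; 1.04 in limma on log2(TPM + 1) and 1.02 with the effective length offset) and JAG2 (1.003 ± 0.11) rose, and edgeR's adjusted p was at most 2.42e-06 for the Hippo/YAP and Notch genes named.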

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

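The tests on transcripts without a gene symbol, the within-group comparison of GC slopes, the GC correction, and those on the depth, the control levels and the 6-library levels of luminal genes were chosen after the results were seen.

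Reads on transcripts without a gene symbol, which no comparison above uses, took 0.680 ± 0.0109% of the control and 0.717 ± 0.0169% of the knockdown libraries (SD, n = 3 each), a difference of 0.0369 percentage points with each knockdown library above each control library (exact two-sided permutation p = 0.1, the smallest possible). Of 700 such transcripts tested singly with edgeR, 22 were higher and 13 lower in the knockdown libraries, beside 3189 calls among 53695 transcripts in all.

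GC-rich transcripts were lower and GC-poor transcripts higher in the knockdown libraries. Libraries of one group differed in their slope on GC content by up to 0.904 of the gap between the group means. A bias that varies from library to library, as amplification or fragmentation can give, could cause this. The slopes also followed the replicate numbers, replicate 2 being highest and replicate 3 lowest in both groups (0.16 and 0.0051 in control, 0.0011 and -0.15 in knockdown). Each knockdown library lay below the control library of its number. An effect shared by number beside a shift between groups would give the same range, so the ratio cannot tell these apart. As the whole cause of the calls such a bias is argued against, since 83.7% of the genes past the threshold kept their call and direction after the GC correction. The corrected fit called 7137 genes in place of 6501 but did not keep 1062 of those (5442 stayed called, 5439 of them in the same direction), and for these a technical and a biological origin were not separated. Whether part of the trend itself follows the knockdown stays open, since a real change in GC-rich genes would be removed by the same correction.

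In 6 libraries labelled MCF-7, CDH1, ESR1, PGR and TFF1 were near 0 and VIM was at 1424 CPM or more. Elsewhere in the luminal list, KRT7, KRT8, KRT18 and XBP1 averaged between 89.0 and 197 CPM over the 6 libraries. The remaining members averaged between 0.724 CPM (AR) and 14.2 CPM (KRT19), with GATA3 at 3.80 and FOXA1 at 5.86 CPM. Depth is argued against, because a gene at 10 CPM would have had 149 reads in the shallowest library, and so is a loss from the index, because each of CDH1, ESR1, PGR and TFF1 had at least 1 listed transcript of over 400 bases. The knockdown is argued against as well, because the highest of these 4 genes in any control library was 1.14 CPM. Whether all 6 libraries came from cells without a luminal profile, either another line or a changed derivative of the named one, stays open. These 4 genes were picked because they were seen near 0, so their highest value in the 6 libraries (1.14 CPM) restates the pattern, and the luminal list as a whole was not set against other cells.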

How the results depend on the processing

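The GC correction was chosen after the results were seen, and every other setting before. ZNF408 stayed lower and past the threshold under all settings (log2 fold change -0.80 to -0.53). The counts below cover every gene the naming rule takes, except ESR1 and PGR, which the main fit did not test, and 14 named outside it, 179 in all, of which 160 were past the threshold. Of 3205 values under other settings 3114 kept their direction and side of the threshold, 41 lost the threshold, 11 gained it and 39 changed sign. Of the sign changes 38 were in 14 genes not past the threshold, and 1 was in MICB, counted by gene ID (-0.019). CIITA changed sign with limma on log2(TPM + 1) (-0.19) and the effective length offset (-0.33), CD14 with the same 2 (-0.039 and -0.21), CDH1 with the first (-0.88), TTC39B with both (-0.018 and -0.065) and the GC correction (-0.12), and CD8A with both (-0.063 and -0.088), limma-voom (-0.077) and the replicate block (-0.029). KRT7 did so with both (-0.14 and -0.19) and with no filter on low counts (-0.0075) and was higher past the threshold after the GC correction (0.23, adjusted p = 3.94e-05, 3.94e-05 to 0.999 over the alternatives), and EPCAM changed sign with no filter (-0.0031) and the GC correction (-0.050). Leaving out single libraries turned the sign of 12 genes, with log2 fold changes of TAP1 -0.033 to 0.12, CD8A -0.38 to 0.34, CD68 -0.028 to 0.061, CD14 -0.21 to 0.30, EGFL7 -0.012 to 0.20, LPCAT3 -0.10 to 0.035, PLTP -0.11 to 0.43, TTC39B -0.022 to 0.099, KRT7 -0.069 to 0.046, EPCAM -0.082 to 0.091, GATA3 -0.25 to 0.33 and FOXA1 -0.34 to 0.0066. Of the 41 lost calls, 17 came with limma on log2(TPM + 1) and 10 with the effective length offset. COL1A1 lost its call after the GC correction (log2 fold change from -0.34 ± 0.11 to -0.11 ± 0.079, so the change itself shrank) and without control replicate 1 or 2 or knockdown replicate 1 or 3. After that correction KRT18 was at -0.19 (from -0.40) and AXL at -0.091 (from -0.23). The mean CPM filter gives no value for named genes below it.

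Lower genes and calls in all moved most with limma on log2(TPM + 1), which gave 1675 lower genes and 410 changed at least 2-fold, and raised the share of higher genes from 49.5% to 57.9%. The cause was not tested. A mean CPM of at least 5 gave 303 genes changed at least 2-fold, with 11233 genes tested. Lists past the threshold numbered 3 with an estimated correlation and 33 with fry, which asks another question. The estimated correlations ran from -0.052 for fatty acid synthesis and lipid storage to 0.54 for mitochondrially encoded genes. Both of these lists lost their call, so members that move together cannot account for every lost call. NF-kB targets, at an estimated correlation of -0.035, still went from a camera adjusted p of 4.78e-09 to 0.0399. The drop from 21 lists to 3 therefore cannot be read as a measure of how far members move together. What else raised the p-values with an estimated correlation was not tested. The effective length offset kept 4147 of the 6501 calls in the same direction and called 4401, and moved higher genes most, to 2154. Leaving out single libraries gave 2599 to 3209 higher genes, 2717 to 3275 lower genes, 592 to 684 changed at least 2-fold and 18 to 25 lists.

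With the replicate number as a block, 3786 genes were higher and 3862 lower, 637 changed at least 2-fold and 18 lists passed. By the labels, same-numbered libraries share no more than a number. Their deviations correlated at -0.00491, 0.168 and 0.0634. Of the 6 libraries, 3 correlated best with their own number, a hint from the data alone, for which no chance level was computed. The GC slopes had the same order by number in both groups. Libraries 2 and 3 differed most within each group (chi-square per degree of freedom 7.07 in control and 7.27 in knockdown). Whether the numbers mark a shared batch stays open. With 10 splits of the 6 libraries into 3 and 3, a share under 0.05 is out of reach. The real split gave 6501 genes, 617 changed at least 2-fold and 21 lists, and 1 of the 10 splits reached each value, the real one. The highest of the other 9 gave 0 genes by edgeR (91 to 691 genes at an unadjusted p under 0.05), 0 changed at least 2-fold and 14 lists. Each of those 9 mixes control and knockdown libraries on both sides, so part of the group difference remains in it. They therefore cannot show how often lists pass without a real difference. The filter on low counts removed ESR1 and PGR.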

Other observations

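Both tests reported for sterol genes below were set before their results were seen, although ABCA1 and MYLIP had been seen.

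Signalling and vascular lists held members that moved apart, as all genes tested did (3217 higher and 3284 lower of 14269). Among TGF-beta and BMP signalling genes, 10 rose, 4 fell and 10 did not pass of 24 (10 and 5 adjusted over the list alone), with SKIL (1.15 ± 0.088, and 0.75 with the effective length offset) and TGIF1 (0.92 ± 0.066), known as repressors of the pathway, higher and BMP4, a ligand gene, lower (-1.17 ± 0.072). The median was 0.31 (camera adjusted p = 0.0566, adjusted p = 0.258 with an estimated correlation). With the GC correction 13 of the list rose and 4 fell. It then passed camera's threshold (adjusted p = 0.0269), but not with an estimated correlation (0.152). Of 14 Wnt targets and regulators, 6 rose, 1 fell and 7 did not pass (6 and 2 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.174, adjusted p = 0.461 with an estimated correlation). WNT5A (0.46 ± 0.074) rose and SP5 (-0.98 ± 0.17) fell, and both calls were lost with the effective length offset (adjusted p = 0.267, 4.01e-06 to 0.267 over the alternatives, and 0.149, 1.53e-06 to 0.193 over the alternatives) and in limma on log2(TPM + 1), SP5 being at -0.64 after the GC correction. CCND1 rose (0.16 ± 0.045, and 0.27 after the GC correction), a call lost in both (adjusted p = 0.837 with the offset, 3.53e-07 to 0.837 over the alternatives) and without control replicate 1 (0.0581). Of 22 angiogenesis and Norrin/Wnt retinal vasculature genes, 3 rose, 7 fell and 12 did not pass (3 and 8 adjusted over the list alone). The median was -0.099 (camera adjusted p = 0.547, adjusted p = 0.566 with an estimated correlation). VEGFA rose from 238 ± 6.46 to 420.4 ± 12.8 CPM (0.82 ± 0.051) and NRP1, a VEGF co-receptor gene, rose too (0.49 ± 0.047). EPHB4 fell (-0.48 ± 0.080, and -0.26 after the GC correction), but not with the effective length offset (adjusted p = 0.112, 1.81e-08 to 0.249 over the alternatives) or in limma on log2(TPM + 1). Hypoxia and glycolysis genes split, as 9 rose, 13 fell and 8 did not pass of 30 (also 9 and 13 adjusted over the list alone, camera adjusted p = 0.828, adjusted p = 0.845 with an estimated correlation), with a median of 0.044 and camera's direction down. The pyruvate kinase gene PKM fell from 2319 ± 43.2 to 1291 ± 25.1 CPM (-0.85 ± 0.041), and P4HA2, a collagen prolyl hydroxylase gene, rose (1.20 ± 0.067).

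Among nuclear-encoded oxidative phosphorylation genes, 3 rose, 12 fell and 14 did not pass of 29 (also 3 and 12 adjusted over the list alone), with SDHA (-0.37 ± 0.059), CYC1 (-0.41 ± 0.069), ATP5F1B (-0.27 ± 0.045) and UQCRC1 (-0.34 ± 0.057) lower. The last 2 lost their calls in limma on log2(TPM + 1) (adjusted p = 0.0813, 2.46e-09 to 0.0813 over the alternatives, and 0.107, 1.20e-07 to 0.107 over the alternatives). After the GC correction CYC1 was at -0.18 and UQCRC1 at -0.17, SDHA was at -0.23 in limma on log2(TPM + 1), and ATP5F1B at -0.17 with the effective length offset. The median was -0.11 (camera adjusted p = 0.0632, adjusted p = 0.373 with an estimated correlation). The list passed camera's threshold after the GC correction (adjusted p = 0.0136, median -0.10), but not with an estimated correlation (0.218). Of 42 ribosomal protein genes, 11 rose, 9 fell and 22 did not pass (also 11 and 9 adjusted over the list alone), RPL10A being higher (0.41 ± 0.053) and RPSA (-0.48 ± 0.046), RPS14 (-0.28 ± 0.047) and RPS2 (-0.30 ± 0.053) lower, although pseudogene copies can share their reads. After the GC correction RPS2 was at -0.13, and 20 of the list rose and 8 fell. The median was 0.071 (camera adjusted p = 0.572, adjusted p = 0.839 with an estimated correlation). Of 15 markers each of T or natural killer cells and of B or myeloid cells, 2 and 3 had enough reads to be tested and 0 passed the threshold of edgeR, DESeq2 or limma-voom in either list, or an unadjusted p of 0.05. These were TRAC (-0.51 ± 0.40) and CD8A (0.027 ± 0.35), and CSF1R (-0.53 ± 0.32), CD14 (0.069 ± 0.36) and CD68 (0.034 ± 0.068). After the GC correction CD68 was higher (adjusted p = 0.0111, 0.0111 to 0.940 over the alternatives). Fibroblast markers had 3 tested, of which PDGFRB rose (1.23 ± 0.14) and FBLN1 (-0.58 ± 0.099) and COL1A1 (-0.34 ± 0.11, but -0.55 in limma on log2(TPM + 1) and -0.61 with the effective length offset) fell, the last in neither the GC-corrected fit nor 4 of the 6 fits without a library, and FBLN1 not with the effective length offset (adjusted p = 0.205, 5.67e-07 to 0.375 over the alternatives) or limma on log2(TPM + 1). Of 6 endothelial markers tested, 3 rose, 0 fell and 3 did not pass (also 3 and 0 adjusted over the list alone): ESAM (from 266 ± 13.3 to 361 ± 25.2 CPM, 0.44 ± 0.060), KDR (0.77 ± 0.15) and TIE1 (0.47 ± 0.11), the TIE1 call being lost with the effective length offset (adjusted p = 0.316, 2.98e-06 to 0.316 over the alternatives) and in limma on log2(TPM + 1). EGFL7 did not pass (0.11 ± 0.10), but did after the GC correction (0.44, adjusted p = 1.89e-05, 1.89e-05 to 0.935 over the alternatives). The median was 0.28 (camera adjusted p = 0.0970, adjusted p = 0.361 with an estimated correlation). With the GC correction 4 of the endothelial list rose and 0 fell, at a median of 0.51. That list then passed camera's threshold (adjusted p = 0.0378), but not with an estimated correlation (0.152).

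The 22 sterol genes past the threshold had a median log2 fold change of -1.05, and of -0.97 after the GC correction, which argues against library GC bias. A hypothesis of sterol surplus, in which oxysterols activate the nuclear receptor LXR and switch off SREBP2, came from the rise of the LXR targets ABCA1 and MYLIP (2.31 ± 0.12), the latter chosen after its values were seen. Of 6 other LXR targets (SMPDL3A, LPCAT3, NR1H3, PLTP, APOE and TTC39B), which it predicted to rise, 0 rose and 0 fell by edgeR, DESeq2 or limma-voom. Their edgeR log2 fold changes ran from -0.26 to 0.46. This argues against a general rise of LXR targets as far as few genes can. PLTP and APOE averaged 0.867 and 2.36 CPM, and a seventh, ABCG1, had too few reads to be tested. Whether these genes respond to LXR in these cells was not tested, so a sterol surplus that leaves them unchanged stays open. Under other settings NR1H3, which had an unadjusted p under 0.05 in edgeR, was lower past the threshold in 4, SMPDL3A was higher without control replicate 1 (adjusted p = 0.0404, 0.0404 to 0.478 over the alternatives) and APOE after the GC correction (0.0296, 0.0296 to 0.604 over the alternatives). How ABCA1 and MYLIP rose without them stays open, and so does a lower demand for sterols in cells with fewer S phase and mitotic transcripts, which was not tested.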
